A study of Mus musculus with 14 samples.

How the data were processed

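The values were log2 signals on Affymetrix mouse whole-genome arrays, which the submitters had produced by robust multi-array averaging (RMA) in Partek 6.5. They had amplified 50 ng of RNA per library with the NuGEN Ovation V2 kit and hybridized biotin-labelled product. The mice were an F2 of 129Sv and C57BL/6. No raw scans were used here, and the values were taken as deposited. Genome positions of the probe sets, the deleted exons of Tfrc and hybridization dates are not given in the sources used here.

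The table held 45101 probe sets for 14 libraries, and no column lacked a sample. Of the probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none. Control probe sets numbered 64, of which 13 with a gene symbol were left out. The remaining 34945 probe sets covered 18193 genes, 9010 of them with more than 1 probe set, and each gene was represented by its probe set with the highest mean over all arrays. Dim probe sets were kept, and the limit for a gene not above background, the 25th percentile of each array, was chosen after the data had been seen. Each library was assigned to a group by its title and genotype, which disagreed with the source name in the library labelled Tfr1-null 3 weeks 1.

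Differences were tested with limma (lmFit and eBayes, default settings), with a mean for each of 4 groups and 1 shared estimate of spread per gene. The contrasts tested were Tfr1-null against control at 3 weeks and at 10 weeks, the difference between these, and 10 weeks against 3 weeks in each genotype. P values were adjusted by Benjamini-Hochberg over all genes of a contrast, and adjusted p under 0.05 counted as called. The residual degrees of freedom were 10 with a prior of 2.72 for all 14 libraries, and 8 with a prior of 2.80 for 12 libraries, with a median residual SD of 0.202 and 0.188 log2 units. SE is the standard error of a contrast from the moderated spread of that gene.

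Gene lists numbered 17, with 11 further lists of markers of other cells, 28 in all, naming 568 genes of which 522 were measured. The gene lists were dopaminergic neuron identity; iron uptake, storage and export; iron-sulfur cluster and heme synthesis; respiratory chain complex I; complexes II to V; the tricarboxylic acid cycle; glycolysis; targets of hypoxia-inducible factor; autophagy and mitophagy; the amino acid and integrated stress response; endoplasmic reticulum chaperones; oxidative stress and ferroptosis defence; neuronal injury; p53 targets and apoptosis; immediate early genes; synaptic vesicle and neurotransmission; and cholesterol synthesis. Marker lists covered microglia, astrocytes, oligodendrocytes, their precursors, endothelial cells and pericytes, ependymal and choroid plexus cells, erythrocytes, and GABAergic, glutamatergic, cholinergic, and serotonergic and noradrenergic neurons. Lists were tested with camera at a preset correlation of 0.01 against all genes tested, adjusted over the 28 lists of a contrast. Camera with a correlation estimated from each list, and fry, were run beside it.

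The groups, tests, lists, most alternatives and the rule for naming genes were set before the data were examined. The rule names Tfrc; for each genotype contrast the 10 genes with the largest rise and the 10 with the largest fall among called genes whose Tfr1-null libraries all lie on one side of all controls of that age, or 5 per direction with the smallest p if none is called; and 5 per direction for the interaction and age contrasts, or 3 if none is called. It adds up to 4 called members of each list, or 2 with the smallest p, and Th, Slc6a3, Slc18a2 and Ddc. Clones and predicted genes without a name were passed over. Other list members named as examples were chosen after their values were seen. The fit to 12 libraries, without the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1, was added after their Tfrc values had been seen.

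In a simulation with known changes in 50 genes per size, limma at these group sizes recovered 38% of changes of 0.5 log2 units at 3 weeks, 72% of changes of 1 and 94% of changes of 2, with 9 false calls. At 10 weeks it recovered 28%, 82% and 96%, with 7 false calls. With 1 wrong label at each age it recovered 0% at every size, and with the 2 wrong libraries left out 54% of changes of 1 log2 unit at 3 weeks and 72% at 10 weeks. The simulation changed few genes and drew independent noise of one spread for both ages, so these shares need not hold for the data. With the libraries as labelled, limma called 220 genes at 10 weeks. Camera called the 1 list that had been shifted and 0 of 20 unchanged lists.

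The computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.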

Results

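The data were 14 Affymetrix mouse expression arrays of ribosome-bound mRNA from dopaminergic neurons of the ventral midbrain. These neurons make dopamine, and their loss underlies the motor signs of Parkinson's disease. In RiboTag mice a chosen cell type carries an epitope tag on a ribosomal protein, so its ribosomes and their mRNA can be pulled out of a lysate of the whole tissue. Tfr1, encoded by Tfrc, is the receptor that brings transferrin-bound iron into cells, and the Tfr1-null animals lacked it in dopaminergic neurons. Controls were heterozygous for the Tfr1 allele. Both genotypes were sampled at 3 weeks, which the submitters call early neurodegeneration, and at 10 weeks, which they call late. There were 3 control and 4 Tfr1-null libraries at 3 weeks, and 4 control and 3 Tfr1-null libraries at 10 weeks. The labels do not say whether the replicates were separate animals, so some may be technical. No library of the input lysate was in the series, so enrichment over whole tissue was not measured.

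The array medians lay between 6.41 and 6.47 log2 units at 3 weeks and between 7.36 and 7.43 at 10 weeks. The 25th percentiles lay between 4.33 and 4.41 at 3 weeks and between 5.45 and 5.54 at 10 weeks. The deposited values carry no detection calls, so a gene is taken as not above background in a group where every library lies under the 25th percentile of its own array. A change against such a group is a bound, given as at least the difference from that percentile. Of the genes called in the fit to 12 libraries described below, this held for the dimmer group of 17 of 335 at 3 weeks and 67 of 2015 at 10 weeks. Pairs of libraries of one age correlated at 0.989 to 0.996 across probe sets at 3 weeks and at 0.968 to 0.986 at 10 weeks. Pairs from different ages correlated at 0.970 to 0.985. High Eif2s3y and Kdm5d, which lie on the Y chromosome, with low Xist, the RNA of the inactive X chromosome, gave a male pattern in 1 of 7 libraries at 3 weeks and in 7 of 7 at 10 weeks. The number of arrays limits the precision of every comparison.

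Tfrc, the targeted gene, was read in each library first, as a check of the labels. The array carries control probe sets for the 5′ end, the middle and the 3′ end of the Tfrc transcript. In the 3 control libraries at 3 weeks the 5′ probe set read 9.59, 9.50 and 9.56 log2 units, and in Tfr1-null 3 weeks 2 to 4 it read 7.13, 7.73 and 6.88. The middle probe set ran the other way, at 8.81, 8.80 and 8.86 in those controls and at 10.88, 10.70 and 10.98 in those Tfr1-null libraries. At 10 weeks the middle probe set read 11.39, 11.69 and 11.50 in the 3 Tfr1-null libraries and 9.34, 9.17 and 9.86 in control 10 weeks 2 to 4. The corresponding 5′ values were 7.79, 8.34 and 9.29 in Tfr1-null and 10.15, 9.63 and 10.44 in control. The Tfr1-null libraries thus carried less signal at the 5′ end of the transcript and more in its remaining part.

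For 2 libraries the Tfrc pattern went against the label. The library labelled Tfr1-null 3 weeks 1 read 9.67 at the 5′ probe set, 8.82 at the middle and 9.19 at the 3′ end, beside means of 9.55, 8.83 and 9.23 in the 3-week controls. Its title and genotype say Tfr1-null, whereas its source name says control. The library labelled control 10 weeks 1 read 8.55, 11.43 and 11.31, on the Tfr1-null side of the other 10-week controls at all 3 probe sets. Which exons were deleted and which probe sets lie in them is not given in the sources used here, and a probe set outside the deleted part checks nothing. No library was moved to another group. For each comparison the count of genes and the lists called are given with all 14 libraries as labelled, and with 12 libraries, leaving out these 2. Many values of single genes, and of lists not called, are given from the 12 libraries alone. The 12-library fit was chosen after the Tfrc values had been seen.

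As labelled, the middle probe set was 1.52 log2 units (SE 0.54) higher in Tfr1-null at 3 weeks and 1.58 (SE 0.54) higher at 10 weeks, and the 5′ probe set differed by -1.70 (SE 0.61) and -1.22 (SE 0.61). None of these passed limma, with adjusted p from 0.142 to 0.288 at 10 weeks and of 1.00 at 3 weeks. Without these 2 libraries the middle probe set rose by 2.03 (SE 0.16, adjusted p = 9.36e-05) at 3 weeks and by 2.07 (SE 0.16, adjusted p = 4.57e-05) at 10 weeks. The 5′ probe set fell by 2.31 (SE 0.35, adjusted p = 0.00497) and by 1.60 (SE 0.35, adjusted p = 0.0153). Two-sided exact permutation tests on the labelled middle probe set gave p = 0.0857 at each age, where 0.0286 is the smallest p that 3 against 4 libraries allow. In the 12-library comparison the same exact test gave p = 0.1 for each probe set and age, which is the smallest that 3 against 3 libraries allow. The 2 libraries were left out because of their Tfrc values, a choice that favours this outcome. The p values of Tfrc from 12 libraries, here and below, therefore test nothing.

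**Figure D1:**
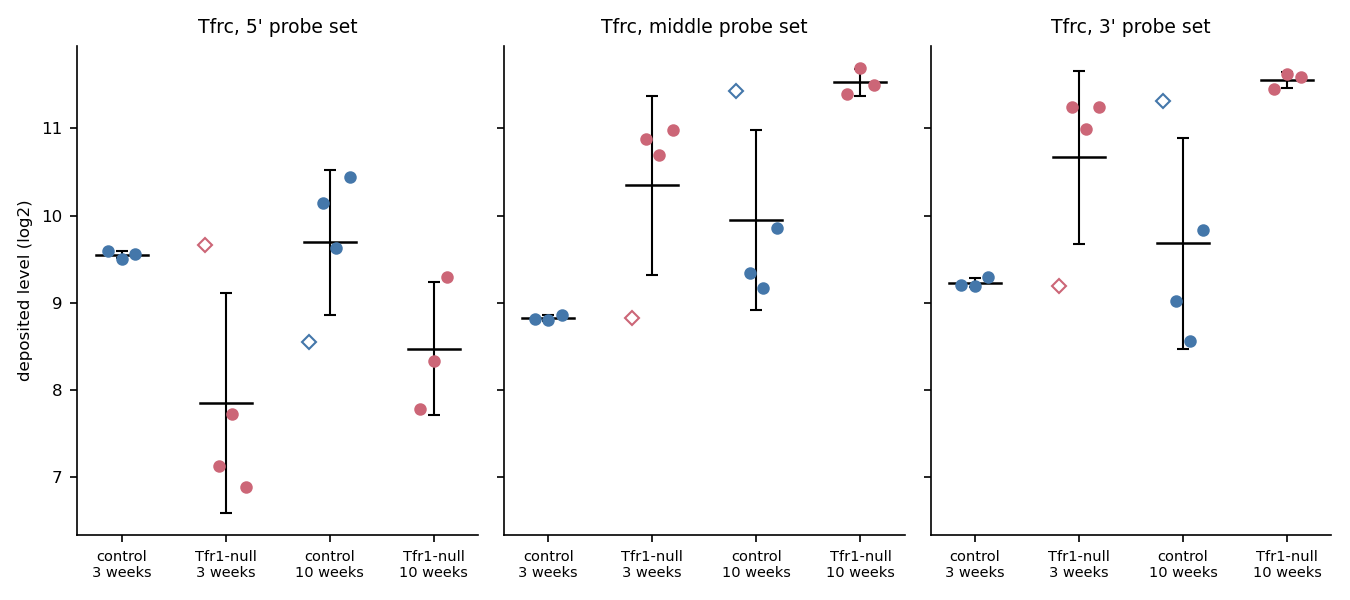
Log2 signal of the 5′, middle and 3′ Tfrc control probe sets in each of the 14 libraries (points), with the mean and SD of each group as labelled. The open diamonds are the library labelled Tfr1-null 3 weeks 1, which reads 8.82 at the middle probe set among controls at 8.80 to 8.86, and the library labelled control 10 weeks 1, which reads 11.43 among Tfr1-null libraries at 11.39 to 11.69.

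The 3-week comparison asks what the loss of Tfr1 changes early in neurodegeneration. With all 14 libraries as labelled, the 29 measured targets of hypoxia-inducible factor averaged 0.77 log2 units higher in Tfr1-null. The 28 genes of the amino acid and integrated stress response averaged 0.68 higher, and the 18 of glycolysis 0.46 higher. The 29 genes of dopaminergic neuron identity averaged -0.20 and the 19 of cholesterol synthesis -0.15. Camera with its preset correlation called these 5 lists and the endoplasmic reticulum chaperones, at adjusted p = 9.79e-20, 9.36e-12, 2.41e-06, 0.000891, 0.000664 and 5.72e-05 in that order. No call held with an estimated correlation, where the smallest adjusted p was 0.467, and fry called 0 lists. Single genes did not pass: limma called 0 genes, with 849 at an unadjusted p under 0.05, and array weights in the same fit gave 589. The smallest p among named genes belonged to Oip5os1 (0.44, SE 0.09), the class II antigen gene H2-Ab1 (0.94, SE 0.19) and the Wnt receptor gene Fzd1 (0.78, SE 0.17). On the lower side stood the sodium channel gene Scnn1a (at least 0.37 lower, as it was not above background in Tfr1-null), Cyp4x1 (-0.91, SE 0.20) and Trim21 (-0.88, SE 0.20), all at an adjusted p of 1.00. Leaving out the library labelled Tfr1-null 3 weeks 1 gave 55 genes.

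Among the largest changes at 3 weeks in the 12-library fit, without the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1, were rises of Hk2, Atf3 and Mmp12 and falls of Anxa1 and Atp2a3. Hk2, which starts glycolysis by phosphorylating glucose, rose by 3.67 log2 units (SE 0.32, adjusted p = 0.0002; 3 libraries per group here and below). Atf3, a transcription factor that stress and nerve injury induce, rose by 4.69 (SE 0.28, adjusted p = 2.1e-05), and Sprr1a, a protein that injured neurons make, by 2.74 (SE 0.35, adjusted p = 0.0018). Mmp12, an elastin-degrading metalloprotease, was not above background in controls and rose by at least 3.20 (adjusted p = 5.06e-06). Among genes that fell, Anxa1, a phospholipid-binding protein, dropped by 4.04 (SE 0.29), the endoplasmic reticulum calcium pump gene Atp2a3 by 3.69 (SE 0.30), the glycogen phosphorylase gene Pygl by 2.97 (SE 0.23), and the lipid droplet coat gene Plin2 by 2.78 (SE 0.13). The other largest rises were Mkrn3, Dach2, Steap1, Triobp, Ighm and Epop, from 2.09 to 3.43, and the other largest falls were Vwce, Tmem232, Tctex1d1, Srpx2, Smpx and Ldoc1, from -3.72 to -2.65. Among these, Mkrn3 and Steap1 were not above background in controls, so they rose by at least 2.72 and 1.87, and Tctex1d1 and Smpx were not in Tfr1-null, so they fell by at least 2.63 and 2.00. The naming rule kept only genes whose Tfr1-null libraries in this fit all lay on one side of every control. That separation thus holds by construction.

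Limma called 335 genes in that fit, 124 higher and 211 lower, of which 306 changed at least 1.5-fold. The count varied with the fit: 918 genes passed when the 6 libraries of 3 weeks were fitted alone and 1360 with array weights. It was 209, 205 and 208 without control 3 weeks 1, 2 and 3, and 206 and 214 without Tfr1-null 3 weeks 2 and 4.

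The targets of hypoxia-inducible factor, the regulator that answers low oxygen and low iron, rose as a group at 3 weeks in the 12-library fit. Of 29 measured, 19 were higher and 0 lower over all genes, and 23 were higher adjusted over the list alone (camera adjusted p = 2.66e-38, and adjusted p = 0.000148 with an estimated correlation). The adenylate kinase gene Ak4 rose by 1.66 (SE 0.09), the mitophagy receptor gene Bnip3 by 1.06 (SE 0.09), and Vegfa, the vascular growth factor, by 1.37. Tfrc, the targeted gene, is itself one of the list, which shares 5 genes with glycolysis and 2 with iron handling. Of 18 glycolysis genes 6 rose, 8 adjusted over the list alone, among them the glucose transporter gene Slc2a1 by 1.04 and the lactate dehydrogenase gene Ldha by 1.05 (camera adjusted p = 2.28e-11, and adjusted p = 0.0109 with an estimated correlation).

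The amino acid and integrated stress response also rose at 3 weeks in the 12-library fit, with 13 of 28 genes higher and 1 lower (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.48e-25, and adjusted p = 0.0109 with an estimated correlation). Chac1, which degrades glutathione, rose by 1.73, the stress transcription factor gene Ddit3 by 1.59, and the serine synthesis gene Psat1 by 1.45, whereas the arginine transporter gene Slc7a3 fell by 1.10. The 20 endoplasmic reticulum chaperone genes averaged 0.29 higher (camera adjusted p = 7.9e-06, but adjusted p = 0.322 with an estimated correlation). Of these Herpud1 alone passed over all genes, at 0.97 (SE 0.19, adjusted p = 0.029), and 7 passed adjusted over the list alone.

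Iron handling showed opposed changes at 3 weeks in the 12-library fit. Slc11a2, the importer of ferrous iron, rose by 1.37 (SE 0.14, adjusted p = 0.0006) and Hmox1, which frees iron from heme, by 1.86 (SE 0.28, adjusted p = 0.0047). Tfr2, the second transferrin receptor gene, fell by 1.61 (SE 0.17, adjusted p = 0.00066). Of 23 genes of the list 3 were higher and 1 lower (camera adjusted p = 0.698), with Tfrc counted among the higher although the libraries were chosen by it. Alas1, the first enzyme of heme synthesis, rose by 0.89 (SE 0.19, adjusted p = 0.041) as the only 1 of 20 genes for iron-sulfur clusters and heme to pass (camera adjusted p = 0.828).

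Most genes of dopaminergic identity did not pass at 3 weeks. In the 12-library fit Th, the rate-limiting enzyme of dopamine synthesis, differed by -0.15 (adjusted p = 0.62), the dopamine transporter gene Slc6a3 by -0.13 (adjusted p = 0.77), the vesicular transporter gene Slc18a2 by -0.34 (adjusted p = 0.18) and Ddc, which makes dopamine from L-DOPA, by -0.29 (adjusted p = 0.20). Of 29 identity genes 2 fell, both over all genes and adjusted over the list alone: Sncg, the gene of gamma-synuclein, by 2.08 (SE 0.16) and the guanylate cyclase gene Gucy2c by 1.66 (SE 0.15). As a list they averaged -0.25 (camera adjusted p = 5e-05, but adjusted p = 0.322 with an estimated correlation). Cholesterol synthesis averaged -0.20 with 0 of 19 past the test and 3 lower adjusted over the list alone (camera adjusted p = 0.000253, but adjusted p = 0.322 with an estimated correlation), and 24 synaptic vesicle genes averaged -0.07 (camera adjusted p = 0.0477, but adjusted p = 0.686 with an estimated correlation).

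The remaining lists were not called by camera at 3 weeks in the 12-library fit. In neuronal injury 3 of 24 rose, namely Atf3, Sprr1a and the cytokine receptor gene Tnfrsf12a by 1.04 (list adjusted p = 0.622). In p53 targets and apoptosis 1 of 23 rose, the death-promoting gene Hrk by 1.07 (list adjusted p = 0.698), and in oxidative stress and ferroptosis defence 1 of 25 fell, the quinone reductase gene Nqo1 by 2.06 (list adjusted p = 0.108). Bnip3 was the 1 of 28 autophagy and mitophagy genes past the test (list adjusted p = 0.755). None of 32 complex I genes, 37 genes of complexes II to V, 17 of the tricarboxylic acid cycle or 17 immediate early genes passed in limma, with list adjusted p of 0.849, 0.807, 0.882 and 0.698.

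**Figure D2:**
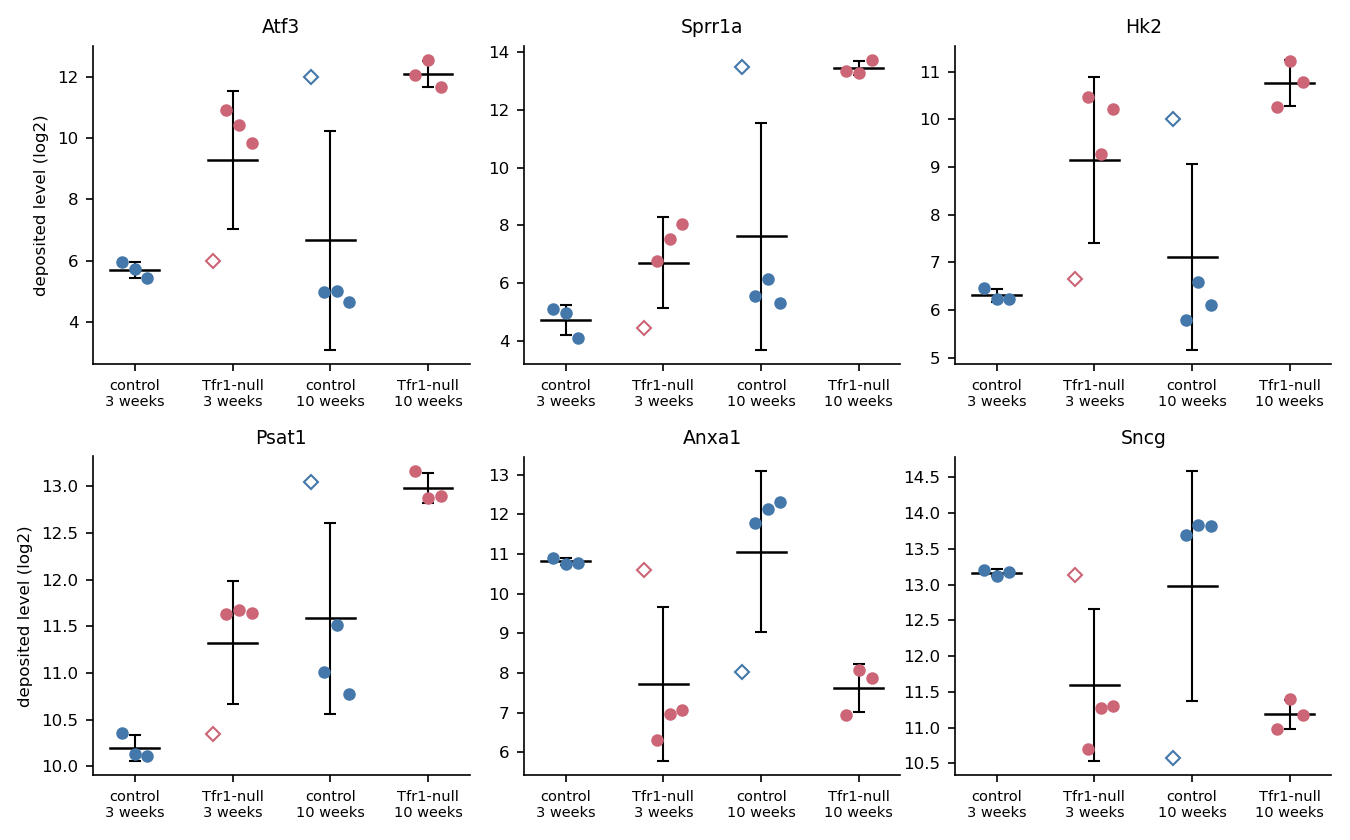
Log2 signal of Atf3, Sprr1a, Hk2, Psat1, Anxa1 and Sncg in each of the 14 libraries (points), with the mean and SD of each group as labelled, and open diamonds for the 2 libraries whose Tfrc pattern goes against the label. Without these 2, Atf3 is higher in Tfr1-null by 4.69 at 3 weeks and at least 6.59 at 10 weeks, and Anxa1 differs by -4.04 and -4.45.

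The 10-week comparison asks the same late in neurodegeneration. With all 14 libraries as labelled, 220 of 18193 genes passed the test, and the single genes named here do not make a theme. Npy, a neuropeptide that injured neurons make, rose by 2.09 log2 units (SE 0.41, adjusted p = 0.038; 3 Tfr1-null and 4 control libraries here and below), and Inhba, which encodes a subunit of activin, by 2.91 (SE 0.58, adjusted p = 0.039). The death-promoting genes Bbc3 and Bcl2l11 rose by 0.98 (SE 0.20) and 1.01 (SE 0.22). The immediate early gene Egr1 rose from a mean of 10.37 in controls to 11.87 in Tfr1-null (SE of the difference 0.33, adjusted p = 0.047). Uqcr11, a subunit of respiratory complex III, fell by 0.60 (SE 0.13), and the mitochondrial peroxidase gene Prdx3 by 0.46 (SE 0.09). The other largest rises were Aldh3b2, Mael, Lce1f, Colec10, Snai2, Foxf2, Hmgb2 and Speer8-ps1, from 1.61 to 2.68. Galm, a galactose mutarotase, fell by 2.66 (SE 0.35), and the transcription cofactor gene Vgll3 by 1.76 (SE 0.23), with Lrmda, Tmem207, Lamp5, Crip2, Cd24a, Pm20d1, Nudt7 and Krt1 between -4.28 and -1.40. Of these, Mael, Lce1f and Snai2 were not above background in controls and rose by at least 1.23, 0.52 and 1.21, and Pm20d1 was not in Tfr1-null, which leaves its fall without a size. The rise of Lce1f was uneven, at 7.16, 5.64 and 5.22 in Tfr1-null 10 weeks 1 to 3. The value of 5.22 lay under its own array's 25th percentile of 5.48.

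Limma called 220 genes at 10 weeks with the libraries as labelled, 108 higher and 112 lower, of which 171 changed at least 1.5-fold, and 3612 had an unadjusted p under 0.05. Several genes with larger values did not pass, as Atf3 at 5.42 (SE 1.57, adjusted p = 0.094), Sprr1a at 5.82 (SE 1.58, adjusted p = 0.082) and Hk2 at 3.64 (SE 0.98, adjusted p = 0.081). The count was unstable: it was 1924 without the library labelled control 10 weeks 1, between 5 and 66 without any 1 other library except the library labelled Tfr1-null 3 weeks 1 and Tfr1-null 10 weeks 2, 3 with the replicate number as a block, 0 when the 10-week libraries were fitted alone, 0 with array weights and 7 without moderation.

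By list, with the 14 libraries as labelled, camera called 9 lists at 10 weeks. Targets of hypoxia-inducible factor averaged 0.76 higher (adjusted p = 1.6e-08), neuronal injury 1.07 (2.11e-06), the integrated stress response 0.73 (6.86e-06), glycolysis 0.51 (9.8e-05), p53 targets and apoptosis 0.47 (0.000585) and immediate early genes 0.40 (0.0141). Complexes II to V averaged -0.20 (2.05e-05), complex I -0.13 (0.000282) and dopaminergic identity -0.32 (0.00289). No call held with an estimated correlation, where the smallest adjusted p was 0.498, and fry in its directional form called 1 list, neuronal injury.

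Genes of neuronal injury were among the largest rises at 10 weeks once the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1 were left out. Sprr1a rose by 7.78 log2 units (SE 0.35, adjusted p = 6.2e-07), Atf3, not above background in controls, by at least 6.59 (adjusted p = 2.7e-07), and Ecel1, an endopeptidase that damaged neurons induce, by 4.24 (SE 0.16, adjusted p = 2.7e-07). Npy rose by 2.59 and the transcription factor genes Jun and Sox11 by 1.82 and 1.81. Of 24 injury genes 12 rose and 0 fell, 14 and 0 adjusted over the list alone (camera adjusted p = 1.84e-11, and adjusted p = 0.00082 with an estimated correlation). The list shares Atf3 with the integrated stress response, Dusp1 with the immediate early genes and Npy with the GABAergic markers. The immediate early genes also share Btg2 with the p53 targets. In the list of p53 targets and apoptosis 7 of 23 rose, 9 adjusted over the list alone: Hrk by 3.38 (SE 0.22), Pmaip1, not above background in controls, by at least 0.92, Apaf1, the core of the apoptosome, by 1.32, and Bcl2l11, Bbc3, Cdkn1a and Mdm2 by 0.95 to 1.22 (camera adjusted p = 0.000354, but adjusted p = 0.298 with an estimated correlation). Pmaip1 read 7.38, 5.31 and 6.52 in Tfr1-null 10 weeks 1 to 3, and 5.31 lies under that array's 25th percentile of 5.49. Of 17 immediate early genes Fosl2, Egr1 and Dusp1 rose, by 1.93, 1.85 and 1.25 (camera adjusted p = 0.00971, but adjusted p = 0.254 with an estimated correlation).

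Limma called 2015 genes in the 12-library fit at 10 weeks, 861 higher and 1154 lower, of which 1342 changed at least 1.5-fold. Mmp12, not above background in controls, rose by at least 6.74 (adjusted p = 1.6e-08). Beside it and the genes above, the largest rises were the desmosome gene Dsp at 4.62, Hk2 at 4.60, Cd68 at 3.87, Inhba at 3.57 and Aldh3b2 at 3.23. Anxa1 fell by 4.45 (SE 0.29). Lrmda stood at -4.75 (SE 0.92), but at -3.51 without control 10 weeks 3 (adjusted p = 0.0073), and its other probe sets gave -1.63 and -0.86. Tmem232, the tight junction gene Cldn2, Crb1, Gstm6 and Tctex1d1 lay from -3.62 to -3.03. Vwce, BB031773 and Gtf2a1l were not above background in Tfr1-null and fell by at least 2.99, 2.13 and 1.89. Fitting the 10-week libraries alone gave 244 genes, the replicate number as a block 1077 and array weights 801. Both ages share one estimate of spread per gene in the 12-library fit, although pairs of libraries correlated less at 10 weeks. With each age fitted alone the order of the counts reversed: 382 genes were higher and 536 lower at 3 weeks, 108 and 136 at 10 weeks. The larger count and the adjusted p values at 10 weeks therefore depend on the shared spread.

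Transcripts of dopaminergic identity were lower at 10 weeks in the 12-library fit. Of 29 identity genes, 9 were lower and 0 higher over all genes, and 15 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.29e-05, but adjusted p = 0.298 with an estimated correlation). A smaller share of RNA from these neurons and lower expression within them could both give such values, and without input lysate they were not told apart. Sncg fell by 2.60 (SE 0.16, adjusted p = 1e-05), Cpne7 by 1.45 (SE 0.30, adjusted p = 0.012), Gucy2c by 1.39 (SE 0.15, adjusted p = 0.00038), and Foxa1, a transcription factor that maintains these neurons, by 0.86 (SE 0.09, adjusted p = 0.00024). The dopamine receptor gene Drd2 fell by 0.85 and Ddc by 0.32 (SE 0.09, adjusted p = 0.049). Th differed by -0.23 (adjusted p = 0.095), Slc6a3 by -0.31 (adjusted p = 0.052) and Slc18a2 by -0.34 (adjusted p = 0.061), which did not pass. As labelled these 3 differed by -0.16, -0.23 and -0.20, with adjusted p of 0.39, 0.22 and 0.49, and Ddc by -0.24 (adjusted p = 0.22). Of 24 synaptic vesicle genes 6 fell, among them Rims1 and Sv2c by 0.77 each and Cplx2 by 0.73, and 2 rose, Unc13a by 0.92 and Syt4 by 0.49 (8 lower and 2 higher adjusted over the list alone; list adjusted p = 0.0583).

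Respiratory chain transcripts were lower at 10 weeks in the 12-library fit. In complexes II to V 10 of 37 fell and 0 rose, 16 lower adjusted over the list alone: Uqcr11 by 0.69 (SE 0.12, adjusted p = 0.0053) and the ATP synthase subunit gene Atp5e by 0.57 (SE 0.09, adjusted p = 0.0034) among them (camera adjusted p = 6.53e-06, but adjusted p = 0.345 with an estimated correlation). In complex I 3 of 32 fell, 9 adjusted over the list alone, with Ndufb2 by 0.76 (SE 0.12, adjusted p = 0.0027) and Ndufa3 by 0.58 (SE 0.10, adjusted p = 0.0051) the largest (camera adjusted p = 0.000358, but adjusted p = 0.345 with an estimated correlation). Ogdh, a subunit of the oxoglutarate dehydrogenase complex, was the 1 of 17 tricarboxylic acid cycle genes to pass, falling by 0.71 (SE 0.14, adjusted p = 0.0087; list adjusted p = 0.474).

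The hypoxia, glycolysis and stress lists rose at 10 weeks in the 12-library fit as well. Of 29 hypoxia-inducible factor targets 21 rose, 24 adjusted over the list alone, with Vegfa at 1.87 (SE 0.19) and Hmox1 at 2.14 (camera adjusted p = 4.70e-20, and adjusted p = 0.00082 with an estimated correlation). Glycolysis had 8 of 18 higher, 10 adjusted over the list alone (camera adjusted p = 5.98e-08, and adjusted p = 0.0329 with an estimated correlation). In the integrated stress response 16 of 28 rose, 21 adjusted over the list alone, with Atf5 at 1.91, Ddit3 at 1.88 and Psat1 at 1.88 (camera adjusted p = 2.35e-15, and adjusted p = 0.0329 with an estimated correlation). Of 20 endoplasmic reticulum chaperone genes 5 rose, among them Hspa5, the main chaperone of that compartment, by 0.51 (camera adjusted p = 0.0312, but adjusted p = 0.543 with an estimated correlation).

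Slc11a2 at 0.99 and Hmox1 rose and Tfr2 fell by 0.94 (SE 0.17, adjusted p = 0.0072), and with Tfrc these made 3 of 23 iron genes higher and 1 lower at 10 weeks in the 12-library fit (list adjusted p = 0.311). Alas1 rose by 0.97 and the mitochondrial chaperone gene Hspa9 by 0.71 (SE 0.15, adjusted p = 0.013), whereas Iscu, the scaffold on which iron-sulfur clusters form, fell by 0.54 (2 of 20 higher and 1 lower; list adjusted p = 0.417). Bnip3 rose by 0.88 while the mitophagy receptor gene Fundc1 fell by 0.95 and the autophagy gene Atg7 by 0.72 (1 of 28 higher and 2 lower; list adjusted p = 0.839). Only the brightest Fundc1 probe set passed: the other probe sets gave -0.12 at a like signal (adjusted p = 0.462) and -0.40 (adjusted p = 0.166). In oxidative stress defence Srxn1 rose by 1.02 and 5 of 25 fell, with Nqo1 at -1.23 and Gpx1 at -0.55 (list adjusted p = 0.537). Cholesterol synthesis had 3 of 19 lower, with Fdps at -0.76 (list adjusted p = 0.156).

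Some other genes named above had another probe set, within 1 log2 unit of the brightest in mean signal, that did not pass in the 12-library fit. At 3 weeks these probe sets gave 0.67 for Alas1 and 0.31 for Hrk. At 10 weeks they gave -0.25 for Rims1, 0.73 for Cdkn1a and -0.31 for Crb1, and for genes named from the 14 libraries 0.28 for Lce1f, 0.32 for Snai2, -0.04 for Foxf2, 0.82 for Hmgb2, -0.88 for Galm and -0.22 for Pm20d1.

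**Figure D3:**
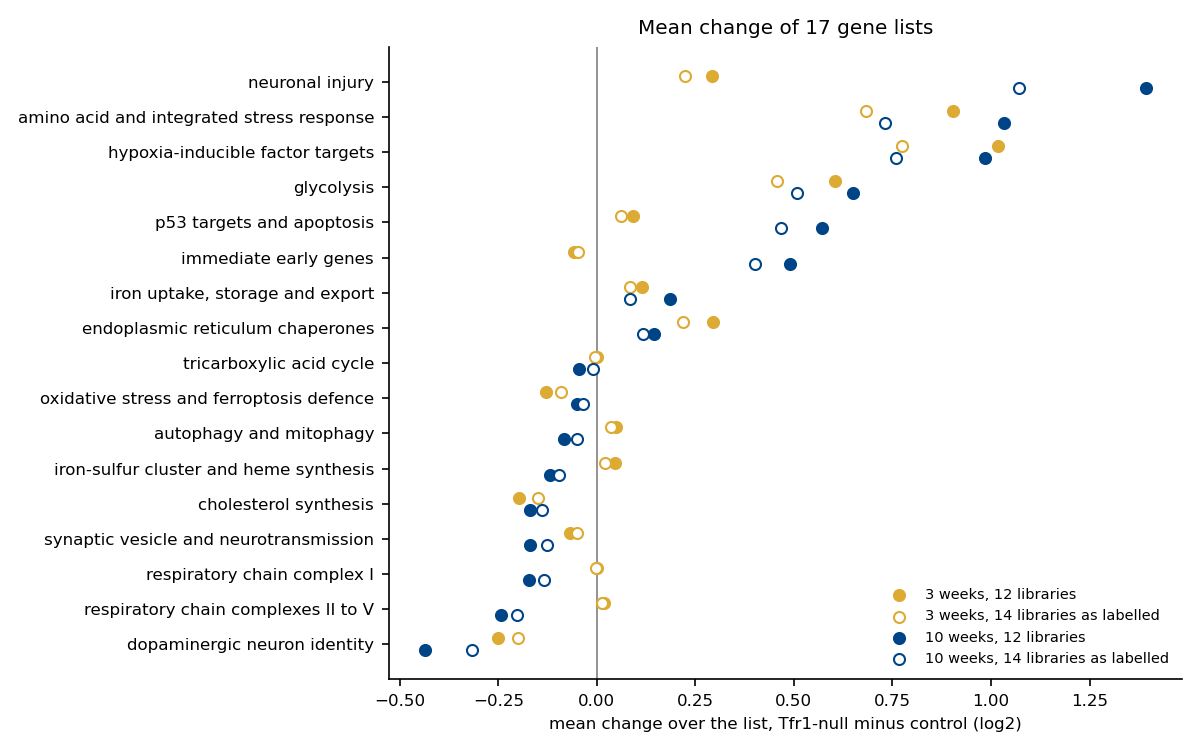
Mean log2 change, Tfr1-null minus control, of the measured genes of each of 17 gene lists at 3 weeks and at 10 weeks, with filled symbols for the 12-library fit and open symbols for all 14 libraries as labelled. Neuronal injury averages 0.29 at 3 weeks and 1.39 at 10 weeks in the 12-library fit, and targets of hypoxia-inducible factor 1.02 and 0.99.

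Markers of other cells were compared in the same way, and the microglia and astrocyte lists were called at 10 weeks beside the groups above. Cd68, a lysosomal protein of microglia and macrophages, rose by 2.01 (SE 0.15, adjusted p = 7.9e-05) at 3 weeks and by 3.87 (SE 0.15, adjusted p = 2.7e-07) at 10 weeks in the 12-library fit, the only 1 of 17 microglia markers past the test at either age. The microglia list averaged 0.46 at 10 weeks (camera adjusted p = 0.0106, but adjusted p = 0.308 with an estimated correlation) and had an adjusted p of 0.807 at 3 weeks. Astrocyte markers averaged 0.29 at 10 weeks with Sox9 at 1.14 as 1 of 17 past the test (camera adjusted p = 0.0286, but adjusted p = 0.566 with an estimated correlation; 0.698 at 3 weeks by camera). Endothelial and pericyte markers averaged -0.21 at 3 weeks with 0 of 15 past limma (camera adjusted p = 0.00597, but adjusted p = 0.322 with an estimated correlation), and their adjusted p was 0.155 at 10 weeks. Prph, an intermediate filament gene of the cholinergic list, fell by 2.18 at 3 weeks and by 2.41 at 10 weeks, the 1 of 7 to pass at each age (list adjusted p = 0.551 and 0.293).

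No other marker list was called in the 12-library fit, with adjusted p given for 3 weeks and then 10 weeks. GABAergic markers had 0.755 and 0.0583, with Npy and the vesicular GABA transporter gene Slc32a1 (0.70) higher at 10 weeks, and glutamatergic markers 0.882 and 0.943, where Barhl1 fell by 0.41 at 10 weeks and its second probe set gave -0.21 (adjusted p = 0.629). Oligodendrocyte markers had 0.190 and 0.537, their precursors 0.551 and 0.710, serotonergic and noradrenergic markers 0.807 and 0.839, and erythrocyte markers 0.666 and 0.613. Ependymal and choroid plexus markers had 0.0735 and 0.0963, where Dynlrb2 fell by 2.15 at 10 weeks. In all 14 libraries as labelled camera called 0 of the 11 marker lists at either age, and Npy was the only marker past limma. In the 12-library fit mean and median differed in sign, without a call, for microglia, cholinergic, glutamatergic, and serotonergic and noradrenergic markers, iron-sulfur cluster and heme synthesis, complex I and autophagy and mitophagy at 3 weeks, and for glutamatergic markers and oligodendrocyte precursors at 10 weeks. In each list called at either age they had 1 sign.

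Whether the effect of the deletion differed between the ages was tested as an interaction. The set of arrays and the sex pattern changed together with age, so a difference between the ages cannot be assigned to age alone. The fit also shares 1 estimate of spread per gene between the ages, although pairs of libraries correlated less at 10 weeks. Without the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1, the rise of injury genes was larger at 10 weeks than at 3 weeks: Sprr1a by 5.04 log2 units (SE 0.49, adjusted p = 0.0029), Ecel1 by 3.56 (SE 0.23, adjusted p = 0.00017) and Npy by 2.90. Atf3 was called as well (adjusted p = 0.033), at 4.69 at 3 weeks and at least 6.59 at 10 weeks, and so was Mmp12, which has no exact size because its controls were not above background at either age. Aldh3b2 differed by 3.41 (SE 0.58) and Inhba by 3.21 (SE 0.50). In the other direction Cldn2 differed by -2.13 (SE 0.36), Aldh1a7 by -1.74 (SE 0.27), the growth factor gene Fgf20 by -1.57 (SE 0.24), Nudt16 by -1.35 (SE 0.16) and Zfp946 by -1.23 (SE 0.17). The injury list averaged 1.10 more at 10 weeks, with 6 of 24 past the test and 15 adjusted over the list alone (camera adjusted p = 4.43e-18, and adjusted p = 0.000232 with an estimated correlation). Camera with the preset correlation also called other lists here, among them microglia (0.400), astrocyte (0.339) and endothelial and pericyte markers (0.398). None of these other lists held with an estimated correlation. The targets of hypoxia-inducible factor differed by -0.03 between the ages (adjusted p = 0.617).

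Limma called 52 genes for this interaction in the 12-library fit, 34 positive and 18 negative, and 0 in all 14 libraries as labelled, where 1360 had an unadjusted p under 0.05. As labelled, the smallest p belonged to Pde1a (0.82, SE 0.13), Atp13a3 (0.79, SE 0.13) and Rtl5 (1.45, SE 0.25), and to Meak7 (-0.88, SE 0.16), Pdgfa (-0.90, SE 0.17) and Enox2 (-0.87, SE 0.18). Their adjusted p was 0.418 at the lowest, and camera called 5 lists, of which 0 held with an estimated correlation (smallest adjusted p = 0.319). The count of 52 fell to 4 with the replicate number as a block and 24 without moderation, and was 9, 10 and 22 without control 3 weeks 1, 2 and 3, 18, 12 and 11 without Tfr1-null 3 weeks 2, 3 and 4, 109 without Tfr1-null 10 weeks 2 and 92 without control 10 weeks 4. At least 52 genes were called in 6 of 100 splits of the same libraries, the real one among them. A split that mixes the genotypes at one age can turn the effect at the other into an interaction, so this share decides nothing. All 14 libraries gave 48 without the library labelled control 10 weeks 1.

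The genes called at the 2 ages overlapped. With 12 libraries, 81 genes were higher at both ages, where 5.87 would be shared if the calls were independent, and 155 were lower at both, where 13.4 would be. The 2 genes called in opposite directions, named after their values were seen, were Cd44, a hyaluronan receptor gene, at -1.03 and then 1.78, and Meak7 at 0.51 and then -0.48. Both ages share one estimate of spread in that fit. With each age fitted alone, 44 genes were higher at both ages against 2.27 expected and 87 lower against 4.01. Of the 335 genes called at 3 weeks 322 had the same sign at 10 weeks. Across all genes the changes at the ages correlated with a Pearson r of 0.507 and a Spearman rho of 0.314, genes not being independent replicates.

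The age comparisons ask what differs between 10 and 3 weeks within a genotype. With all 14 libraries as labelled, the median gene was 0.88 log2 units higher at 10 weeks in controls and 0.86 higher in Tfr1-null, so changes are given relative to that shift, with the adjusted p after quantile normalization of all 14 arrays together. In controls Il33, an alarm cytokine of glia, lay 3.05 above the median shift (adjusted p = 0.000346), and the Y-linked Eif2s3y 4.10 above it (adjusted p = 0.0114), while Xist, not above background there at 10 weeks, lay at least 3.04 below it (adjusted p = 0.0103). In Tfr1-null Ecel1 lay 4.17 above (adjusted p = 0.00274), Sprr1a 5.88 above (adjusted p = 0.0239) and Mmp12 5.02 above (adjusted p = 0.0777), with 12 libraries at 3.79 (adjusted p = 1.71e-05). The naming rule, applied to the deposited values, also gave in controls Kdm5d at 3.86 relative to the shift, and Gda, Ears2 and Galntl6 at -1.99, -1.91 and -1.56. Abca8a and Cox7c, not above background in controls at 3 weeks, lay at least 2.09 and 1.90 above the shift, and Tcfl5, not above background at 10 weeks, at least 0.21 below it. The Cox7c probe sets were dim, with means of 5.17 and 3.40 over all arrays. The list of complexes II to V averaged 12.5 in control 3 weeks 1, so these probe sets may not measure the Cox7c mRNA. In Tfr1-null the rule gave Eif2s3y and Kdm5d, not above background at 3 weeks, at least 4.93 and 4.71 above the shift. Xist, Otor and Steap4, not above background at 10 weeks, lay at least 4.35, 0.52 and 1.49 below it, and Aldh1a7 and Cdca8 at -2.59 and -2.16. Of the genes called after quantile normalization, Uty (2.63) and Tdrd1 (-1.86) were among the 5 largest in their direction in controls and Cox7c and Galntl6 were not, and in Tfr1-null Uty and Tcfl5 were and Mmp12 and Cdca8 were not. In Tfr1-null Uty, not above background at 3 weeks, lay at least 2.30 above the shift, and Tcfl5, not above background at 10 weeks, at least 0.94 below.

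By list, after quantile normalization and as labelled, the preset correlation gave calls that an estimated one did not keep. Cholesterol synthesis averaged -0.34 in controls, with 10 genes lower at 10 weeks (camera adjusted p = 0.000406, but adjusted p = 0.546 with an estimated correlation), and -0.32 in Tfr1-null with 8 lower (adjusted p = 0.00399, but adjusted p = 0.572 estimated). Markers of oligodendrocyte precursors averaged -0.61 (adjusted p = 0.0016, but adjusted p = 0.546 estimated) and -0.59 (adjusted p = 0.0142, but adjusted p = 0.572 estimated), and cholinergic markers 0.46 in controls (adjusted p = 0.0375, but adjusted p = 0.546 estimated). In Tfr1-null the injury list averaged 1.04 with 9 genes higher (adjusted p = 0.000492), astrocyte markers 0.50 (adjusted p = 0.00138), the integrated stress response 0.50 (adjusted p = 0.00399), dopaminergic identity -0.34 (adjusted p = 0.00399), immediate early genes 0.57 (adjusted p = 0.00904), complex I -0.14 (adjusted p = 0.00904) and complexes II to V -0.13 (adjusted p = 0.0107). With an estimated correlation these 7 had an adjusted p of 0.572 to 0.573.

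Camera with the preset correlation made each of these calls in the 12-library comparison too, where the stress response in Tfr1-null averaged 0.28 in place of 0.50. It also called oligodendrocyte markers in controls there (-0.39, adjusted p = 0.0195), and GABAergic (0.45) and microglia markers (0.38) in Tfr1-null (adjusted p = 0.0351 for each). With an estimated correlation the injury list in Tfr1-null alone was called in 12 libraries (adjusted p = 0.00308), and the next smallest were an adjusted p of 0.651 in controls and 0.322 in Tfr1-null. For 3 lists the call in controls ended without the 2 libraries, and as labelled it was lost with an estimated correlation (adjusted p = 0.890 for each). The integrated stress response averaged 0.44 (adjusted p = 0.0092) and then 0.13 (adjusted p = 0.208), dopaminergic identity -0.24 (adjusted p = 0.0174) and then -0.12 (adjusted p = 0.125), and astrocyte markers 0.33 (adjusted p = 0.0375) and then 0.24 (adjusted p = 0.208).

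A list called in 1 genotype alone is not thereby shown to differ between genotypes, which the interaction tests. Limma called 15905 genes in controls and 15560 in Tfr1-null on the deposited values, and 2643 and 3462 after quantile normalization, of which 712 were higher and 897 lower in both genotypes. Age, the set of arrays and the sex pattern changed together, so these differences cannot be assigned to one of them.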

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

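The tests of wrong labels, mixed libraries and swaps, of RNA from microglia and of separate normalization, and every value from 12 libraries, were chosen after the results had been seen.

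In groups of 4 libraries, a library whose gap to its nearest neighbour took up more of the range than Dixon's 95% limit allows was noted, and chance gives this in about 1 in 20 groups. The library labelled control 10 weeks 1 stood apart in Tfrc (gap over range 0.861), and in the list means of glycolysis (0.951), targets of hypoxia-inducible factor (0.869), autophagy and mitophagy (0.900), the integrated stress response (0.973) and neuronal injury (0.924). Control 10 weeks 3 stood apart in oxidative stress defence (0.871) and control 10 weeks 4 in cholinergic markers (0.938). The library labelled Tfr1-null 3 weeks 1 stood apart in 5 Tfrc probe sets (0.880, 0.867, 0.900, 0.874 and 0.868), in the targets of hypoxia-inducible factor (0.882), neuronal injury (0.831) and cholinergic markers (0.918). Tfr1-null 3 weeks 3 stood apart in complexes II to V (0.894). Among 227 named genes, 38 had such a library in the 10-week controls, in 33 of them the library labelled control 10 weeks 1. In Tfr1-null at 3 weeks 29 had one, in 24 of them the library labelled Tfr1-null 3 weeks 1.

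The first pattern is this pair of libraries, whose Tfrc values go against a label. A wrong label is consistent with scores from 0 for control to 1 for Tfr1-null, taken over genes called at the other age: the library labelled Tfr1-null 3 weeks 1 scored 0.0454 over 243 genes, where the other 3-week Tfr1-null libraries scored 0.915 to 1.08, and the library labelled control 10 weeks 1 scored 0.934 over 917 genes, where the other 10-week controls scored 0.0191 to 0.159. Mixed libraries would lie between the genotypes, but in the difference of the middle and 5′ Tfrc probe sets these lay at -0.0277 and 0.953. An exchange of the pair's finished arrays is argued against by their places between 3 weeks (0) and 10 weeks (1), 0.00558 and 0.973. Age and the set of arrays changed together, so these places cannot decide on an exchange made before the arrays were run. No other library stood on the wrong side as a partner for a swap within an age. An error of genotyping, a library from outside the series, and an animal whose deletion had failed stay open, as untested.

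The second pattern is Cd68, higher by 3.87 in Tfr1-null at 10 weeks in the 12-library fit. RNA from more microglia would raise their other transcripts alike, but the median of the 16 other markers was 0.244, with an upper quartile of 0.498 and the highest, C1qa, at 0.916. The median of 6 genes that microglia are known to express strongly (C1qa, C1qb, C1qc, Ctss, Tyrobp and Cx3cr1) was 0.530, and Csf1r and Laptm5, the markers with the highest signal in these controls, stood at 0.55 and 0.17, so the values argue against microglial RNA as the whole cause. A change inside microglia and expression of Cd68 by the neurons may each remain, and neither was tested.

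The third pattern is that nearly all genes were higher at 10 weeks. The array medians of the ages lay 0.897 apart, 12.6 times the widest range within an age (0.0575 at 3 weeks and 0.0710 at 10 weeks), which is consistent with the ages having been normalized separately. The sex of the animals cannot be told apart from age, because 7 of 7 libraries at 10 weeks had a male pattern and 1 of the 3-week controls did. Over 2639 genes that library lay at 0.0251 between the other 3-week controls and the 10-week controls, but 1 library decides nothing. Age itself stays open, as untested.

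An interaction test compared the effect of the deletion between the ages, and beyond the injury list it leaves open whether the effect differed. The array set and the sex pattern changed with age, so the difference in the injury list cannot be assigned to age alone. As labelled, the difference in the lists called with the preset correlation (10 weeks minus 3 weeks) averaged -0.132 for complex I, -0.216 for complexes II to V, 0.848 for neuronal injury, 0.407 for p53 targets and apoptosis and 0.449 for immediate early genes. In the 12-library fit these were -0.171, -0.263, 1.10, 0.479 and 0.550, and microglia markers averaged 0.400, astrocyte markers 0.339 and endothelial and pericyte markers 0.398. Of these lists only neuronal injury held with an estimated correlation, in the 12-library fit. Among the 52 genes of that fit were Sprr1a at 5.04, Mmp12 at 4.01, Ecel1 at 3.56, Aldh3b2 at 3.41 and Inhba at 3.21, and Cldn2 at -2.13, Aldh1a7 at -1.74, Fgf20 at -1.57, Nudt16 at -1.35 and Zfp946 at -1.23. The value of Mmp12 has no exact size, because every control library of the 12 read it under its own array's 25th percentile.

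Probe sets with no gene listed, which the comparisons leave out, also carried signal. Of 9160 tested, limma called 14 at 10 weeks as labelled (10 higher), and in the 12-library fit 14 at 3 weeks (6 higher) and 171 at 10 weeks (85 higher).

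Other splits of the same libraries into groups of the same sizes were fitted the same way. As labelled, the real split called 0 genes at 3 weeks, so all 35 splits reach that by construction and the count tests nothing; the highest other called 178. At 10 weeks 3 of 35 splits, the real one among them, called at least its 220, with 2088 the highest other, so chance is not excluded. These highest splits put the library labelled Tfr1-null 3 weeks 1 with the controls and the library labelled control 10 weeks 1 with Tfr1-null, so they follow a structure of the samples. For the interaction as labelled the real count was also 0, which all 100 splits drawn reach by construction, with 311 the highest other. In the 12-library fit 6 of 100, the real one among them, called at least its 52, with 353 the highest other. That highest split moved only 3-week libraries, so the genotype effect at 10 weeks could count there as an interaction. The share therefore cannot decide whether chance gave the 52. For age, 1 of 35 splits, the real one, reached 15905 in controls (highest other 11760) and 1 of 35 reached 15560 in Tfr1-null (highest other 10946). On these deposited values the array medians of the ages lay 0.897 apart, which sets this split apart for nearly every gene in advance. These counts therefore do not test chance, and no splits were fitted after quantile normalization. In the 12-library fit the 10 splits are too few for a share under 0.05: the real split gave 335 at 3 weeks with 0 as the highest other, 2015 at 10 weeks with 1, 15965 for age in controls with 0, and 15659 in Tfr1-null with 0.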

How the results depend on the processing

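The fits without both doubted libraries (the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1), and those with the source name deciding a label plus 1 library left out, were chosen after the data had been seen. Of the values of single genes called as labelled, 894 kept their direction and side of the threshold, 423 kept only the direction and 1 reversed, and in the 12-library fit 3388, 397 and 1 did. Called lists kept both in 396 comparisons and lost the call in 24 as labelled, and 416 and 60 in the 12-library fit. Dim probe sets near background and 3 or 4 libraries per group limit all of these. Where no construction of the alternative shows it, the cause was not tested.

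The 3-week count of 0 as labelled became 589 with array weights, 178 with the source name deciding, 335 without both doubted libraries and 504 with the source name and without control 10 weeks 1. Leaving out 1 library gave 0 to 55, with 55 without Tfr1-null 3 weeks 1. The 12-library count of 335 became 918 with only the groups of the contrast, 1360 with array weights and 221 above the median, where fewer genes are tested. Leaving out 1 library gave 205 to 412: 209, 205 and 208 without control 3 weeks 1, 2 and 3, and 206 and 214 without Tfr1-null 3 weeks 2 and 4.

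The 10-week count of 220 as labelled became 3 with the replicate block, 0 with only the groups of the contrast, 7 unmoderated, 0 with array weights, 408 above the median, 86 with the mean of probe sets, 487 with the source name deciding, 2015 without both and 2421 with the source name and without control 10 weeks 1. Leaving out 1 library gave 5 to 1924: 6, 7 and 7 without control 3 weeks 1, 2 and 3, 13, 6 and 5 without Tfr1-null 3 weeks 2, 3 and 4, 27 and 11 without Tfr1-null 10 weeks 1 and 3, and 1924, 8, 14 and 66 without control 10 weeks 1, 2, 3 and 4. The 12-library count of 2015 became 1077 with the replicate block, 244 with only the groups of the contrast, 801 with array weights, 3045 over all probe sets and 1342 at 1.5-fold or more, and 1425 to 2128 leaving out 1 library.

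The interaction count of 0 became 52 without both and 143 with the source name and without control 10 weeks 1, and 0 to 48 leaving out 1 library, with 48 without control 10 weeks 1. The 12-library count of 52 became 4 with the replicate block and 24 unmoderated, and 9 to 109 leaving out 1 library: 9, 10 and 22 without control 3 weeks 1, 2 and 3, 18, 12 and 11 without Tfr1-null 3 weeks 2, 3 and 4, 109 without Tfr1-null 10 weeks 2 and 92 without control 10 weeks 4. In the labels, replicates of the 2 genotypes share only a number. Correlations of same-numbered libraries were 0.0276, -0.0338 and 0.0200 at 3 weeks and 0.0880, 0.0118 and 0.0318 at 10 weeks, under the 0.1 taken as pairing. Yet for control 10 weeks 1, 2 and 3 the same-numbered Tfr1-null library was the best match, which held for no such control at 3 weeks. A weak pairing at 10 weeks is therefore not excluded.

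The age counts of 15905 in controls and 15560 in Tfr1-null became 2643 and 3462 after quantile normalization, 3567 and 4662 median centred, both of which remove the shift, 7828 and 7568 above the median and 38702 and 38704 over all probe sets, which count more units. They were 15084 to 16006 and 14760 to 15851 leaving out 1 library.

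Tfrc at 3 weeks, 1.19 and not past the test as labelled, passed at 1.42 with array weights, 1.62 with the source name deciding, 1.61 without both and 1.62 with the source name and without control 10 weeks 1, and lay at 1.02 to 1.61 leaving out 1 library. At 10 weeks it passed at 1.61 without both and 1.61 with the source name and without control 10 weeks 1, and lay at 1.06 to 1.61 leaving out 1 library. In both of these fits libraries were left out because of their Tfrc values, so a pass of Tfrc there tests nothing.

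The lists called as labelled at 3 weeks were 6 by camera, 0 with an estimated correlation, 0 by fry and 0 by fry in either direction, and 5 to 9 leaving out 1 library. At 10 weeks they were 9, 0, 1 and 16, and 7 to 11 leaving out 1 library. For the interaction they were 5, 0, 0 and 0, 8 with the source name deciding, 8 without both, and 5 to 10 leaving out 1 library. In the 12-library fit an estimated correlation kept 3, 4 and 1, fry in either direction called 13, 22 and 13, fry for the interaction 4 and the replicate block 5. Leaving out 1 library there gave 6 to 9, 10 to 14 and 6 to 11.

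Values that reversed were Gda by age in controls with the mean of probe sets (0.127), Atf3 by age in controls without both (-0.823) and with the source name and without control 10 weeks 1 (-0.894), neither an exact size because these 10-week controls all read it under their arrays' 25th percentiles, and Atp5g1 at 10 weeks in the 12-library fit with the mean of probe sets (0.0983). For the interaction of the targets of hypoxia-inducible factor, with a mean of -0.0128 as labelled, camera's test against all genes pointed up (adjusted p = 0.961), and it turned down and passed without Tfr1-null 3 weeks 1 (-0.258) and with the source name deciding (-0.249). Its mean lay at -0.258 to 0.213 leaving out 1 library, the upper value without control 10 weeks 1, where it was not called.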

Other observations

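Unless stated, the tests in this part used 12 libraries, without the library labelled Tfr1-null 3 weeks 1 and the library labelled control 10 weeks 1. That choice was made after the data had been seen, and the subtype prediction itself was written before its result.

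Dopaminergic neurons of the ventral tier of the substantia nigra die first in Parkinson's disease, while those of the dorsal tier and the ventral tegmental area are spared longer. From general knowledge, 9 measured transcripts of the ventral tier and 12 of the dorsal tier and tegmental area were listed, none of them in the lists above. At 10 weeks the ventral tier list averaged -0.774 in Tfr1-null, with 5 genes lower (camera adjusted p = 1.53e-05, and adjusted p = 0.00991 with an estimated correlation). Ndnf, a secreted neurotrophic factor gene, fell by 1.34 (SE 0.15), the collagen gene Col25a1 by 1.19 (SE 0.19), the chromatin organizer gene Satb1 by 0.78 (SE 0.11) and the palmitoyltransferase gene Zdhhc2 by 0.64 (SE 0.14). Grin2c, an NMDA receptor subunit gene, fell by 1.49 at 3 weeks and by 1.72 at 10 weeks. The tegmental list averaged -0.0856 at 10 weeks, with 1 gene higher and 2 lower (adjusted p = 0.380). At 3 weeks both lists were lower, by -0.358 (adjusted p = 0.000173, and adjusted p = 0.0174 with an estimated correlation) and -0.326 (adjusted p = 0.000152, and adjusted p = 0.00991 with an estimated correlation), with 1 gene past limma in each. With all 14 libraries as labelled, the ventral tier list averaged -0.549 at 10 weeks with 1 gene lower (camera adjusted p = 0.0028, but adjusted p = 0.228 estimated). At 3 weeks it then averaged -0.284 with 0 lower (camera adjusted p = 0.00774, but adjusted p = 0.228 estimated). The tegmental list as labelled averaged -0.267 at 3 weeks (camera adjusted p = 0.000193, and adjusted p = 0.0133 estimated) and -0.0775 at 10 weeks (camera adjusted p = 0.300).

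The hypothesis was that loss of Tfr1 may lower ventral tier transcripts more than tegmental ones. The mean change of the ventral tier list minus that of the tegmental list was -0.688 at 10 weeks, in the predicted direction. At 3 weeks it was -0.0324, as both lists fell by like amounts, so no larger fall of ventral tier transcripts was seen there. Only a difference in the other direction had been set to count against the hypothesis, so by that rule the 3-week value decided nothing. Two-sided exact permutation tests of these differences gave p = 0.1 at 10 weeks, the smallest that 3 against 3 libraries allow, and p = 0.7 at 3 weeks. With all 14 libraries as labelled they were -0.471 (exact permutation p = 0.2) and -0.0171 (exact permutation p = 0.8). A loss of ventral tier neurons and lower expression within them could both give such values, and ribosome-bound RNA pooled over neurons does not separate them.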
